A study of Homo sapiens with 26 samples.

How the data were processed

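Bulk RNA and single-cell RNA of both lines were used. The bulk samples were 18 libraries of mRNA, 3 for each line untreated (medium changed 3 days before), after 3 days and after 9 days of drug, the drug renewed every 3 days. Plating was staggered so that RNA of all groups was extracted together, per the labels. The single-cell samples were 8 libraries of 3' tags, 1 for each line untreated and after 24, 48 and 72 h, with the cells of 3 plates pooled into each. Both lines were described as clonal. Line and drug change together, so line differences are differences between line and drug pairs.

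The bulk values were deposited by the authors as TPM summed per Ensembl gene, and the submitters' processing notes name Salmon 1.2.1 and DESeq2 1.26.0. The single-cell values were deposited by the authors as whole-number UMI counts per gene and barcode, and the notes name Cell Ranger 3.0.1 and Seurat 3.0. Both name the build GRCh38. The bulk tables held 60229 genes, of which 59980 identifiers matched a symbol in GENCODE v29, which also gave the coordinates. The single-cell tables held 33694 genes. Read depth is not kept in TPM, so the depth of the bulk libraries is unknown. Between 13388 and 14596 genes reached 1 TPM per bulk library. Correlations between replicates of a group were 0.967 to 0.9789 in PC-9 and 0.972 to 0.9776 in SK-MEL-28.

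Groups, comparisons, gene lists, the rule for named genes and most settings tried as checks were chosen before the data were examined. The plan for counts was an edgeR quasi-likelihood test. As the values were TPM, the planned substitute was used: limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with the trend option of its moderated test, all libraries of a line in 1 fit (6 residual degrees of freedom), and Benjamini-Hochberg adjusted p under 0.05. Genes with at least 1 TPM in at least 3 libraries were tested. The difference between lines was tested as an interaction over all 18 libraries. In the test of sets, 32 biology lists and 4 quality lists were compared with all other genes by camera with its preset correlation of 0.01, and again with an estimated correlation. By fry, each list was tested against no change, without regard to the other genes. Adjustment over the list alone used only the p-values of that list's genes. In simulated TPM with 100 genes raised by log2 1 and 100 by log2 2, the PC-9 day 9 design recovered 89 and 98% with 4.6% false among the called, and the SK-MEL-28 design 90 and 97% with 3.6% false.

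Named genes were, in each bulk comparison, the 5 rises and 5 falls with the largest change among genes with a symbol, adjusted p under 0.05, a mean of at least 10 TPM in 1 group (planned as CPM) and no overlap between groups, the 4 members of a list with the smallest adjusted p as its examples, and a fixed set of 22 genes of signalling, cycling and lineage. For the line difference, the 5 largest terms each way were taken without the overlap rule. In single cells, the 5 highest and lowest ratios at 72 h with at least 50 CPM were taken. Small RNAs and pseudogenes that met the rule are named with their kind. Some genes that met the rule are not reported here.

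Barcodes with at least 500 genes and under 20% mitochondrial counts were kept, from 1668 to 3273 per library, with a median of 14179 to 28705 UMIs per cell. Counts were summed over the cells of a library and scaled to CPM. Ratios of single genes and their ranking used CPM without a pseudocount. List medians used log2 ratios with a pseudocount of 1 CPM and were compared with 10000 random lists matched in 20 bins of mean expression. For cycling, cells with at least 5000 UMIs were thinned to 5000, and a cell with at least 25 UMIs of the 54 matched G2/M genes was called G2/M-high. Clusters used scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and leidenalg 0.10.2 at a resolution of 0.5. Doublets were called in 52 of 7736 PC-9 cells and 17 of 10050 SK-MEL-28 cells, so few that doublets were in effect not removed. TMM factors came from edgeR 4.0.16. In simulated sums, a list raised by log2 1 lay at percentile 100 and an unchanged list at 40.93. No test was made on single cells, having 1 library per group.

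Other settings tried were no expression filter, the replicate number as a block, only the groups compared, a change of at least 1 on the log2 scale, and leaving out each library. In single cells they were other filters, minimums and resolutions, thinning to 3000 UMIs, TMM factors and leaving out called doublets. Chosen after seeing the data were median-of-ratios scaling of TPM (adapted from the planned size factors), a pseudocount of 0.1 TPM, TPM rescaled without mitochondrial-encoded genes, leaving out barcodes under 2% mitochondrial, and the overlap of lines at day 3. The planned edgeR and DESeq2 tests of bulk counts, and a DESeq2 change for the single-cell comparison, need counts and were not run. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.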

Results

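Drug-tolerant cells were profiled in 2 human cancer lines. PC-9 is a lung adenocarcinoma line that depends on the receptor EGFR and was exposed to 5 µM gefitinib, an EGFR inhibitor. SK-MEL-28 is a cutaneous melanoma line that depends on the kinase BRAF and was exposed to 5 µM dabrafenib, a BRAF inhibitor. Bulk RNA was measured in untreated cells and after 3 and 9 days of drug, with 3 libraries per group, and single cells were measured untreated and after 24, 48 and 72 h, with 1 library per time and line. The comparisons address which genes and pathways moved in each line, and how day 9 differed from day 3. Bulk levels are means of 3 libraries in TPM, changes are log2 fold changes of TPM + 1, which understate the change of genes near 1 TPM, and p-values are adjusted over all genes tested by limma unless stated. Nothing in the labels says that the replicates of a group were separate cultures, so the p-values measure only the spread between these libraries.

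In PC-9 cells after 3 days of gefitinib, the transcriptional output of the MAPK pathway fell. Of 21 measured MAPK output genes 18 fell and 1 rose (19 and 1 adjusted over the list alone), with a median log2 fold change of -1.29. DUSP6, a phosphatase that switches off ERK and lies on chromosome 12 (89347232 to 89353271), fell by 2.54 ± 0.15 (SE, n = 3 against 3). SPRY4, a feedback inhibitor of receptor signalling, fell by 1.86, and the ETS factor ETV5 fell by 1.49. PHLDA1 fell by 2.34 ± 0.07. The genes of the cell cycle fell with them. Of 43 S-phase genes 39 fell and none rose (41 adjusted over the list alone, median -0.71), among them TYMS (-0.95), which makes thymidylate. Of 54 G2/M genes 53 fell (53 adjusted over the list alone, median -0.74), among them the spindle checkpoint kinase BUB1 (-0.98 ± 0.05) and TPX2 (-0.92). The proliferation marker MKI67, on chromosome 10 (128096659 to 128126385), went from 71.7 to 48.9 TPM (-0.55 ± 0.08, adjusted p = 0.000477). CDKN2B, a cell cycle inhibitor on chromosome 9 (22002903 to 22009363), rose from 3.23 to 43.6 TPM (3.41 ± 0.13, adjusted p = 3.52e-07). Genes of ribosome biogenesis fell in 28 of 30 cases (29 adjusted over the list alone, median -0.63), among them NOP56 (-1.04). Against the other genes, camera gave adjusted p = 1.62e-12 for MAPK output, 4.27e-21 for S phase, 3.15e-26 for G2/M and 5.44e-15 for ribosome biogenesis. With an estimated correlation between genes these became adjusted p = 0.0668, 0.0724, 0.0725 and 0.0668.

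The lists with most genes higher in PC-9 at day 3 included cholesterol synthesis, antigen presentation, interferon-stimulated, lysosome, mesenchymal and epithelial genes. Of 24 cholesterol synthesis genes 23 rose (23 adjusted over the list alone, median 1.27, camera adjusted p = 7.16e-13, and adjusted p = 0.0719 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate and lies on chromosome 5 (43289395 to 43313512), went from 82.3 to 359 TPM (2.11 ± 0.05, adjusted p = 8.97e-08), and MSMO1 rose by 2.15 ± 0.06. Of 15 antigen presentation genes 14 rose (14 adjusted over the list alone, median 1.18, camera adjusted p = 2.15e-08, and adjusted p = 0.153 with an estimated correlation). The class I gene HLA-B, on chromosome 6 (31269491 to 31357188), went from 14.9 to 177 TPM (3.48 ± 0.07), its partner B2M from 996 to 2780 TPM (1.48 ± 0.04), and the class II chaperone CD74 rose by 2.93 ± 0.09. Of 31 interferon-stimulated genes 21 rose and none fell (22 adjusted over the list alone, median 0.74, camera adjusted p = 7.64e-05, and adjusted p = 0.248 with an estimated correlation), with IFI6 (1.71 ± 0.15) and IFIT3 (1.09) as examples. Lysosome and autophagy genes rose in 22 of 30 cases (24 higher and 1 lower adjusted over the list alone, median 0.74, camera adjusted p = 1.17e-07, and adjusted p = 0.248 with an estimated correlation), including the autophagy protein GABARAPL1 (27.5 to 172 TPM). Mesenchymal genes rose in 11 of 19 cases and fell in 3 (12 and 3 adjusted over the list alone, median 0.57, camera adjusted p = 0.002, and adjusted p = 0.33 with an estimated correlation). Fibronectin, FN1, went from 18.3 to 181 TPM (3.24 ± 0.09), and the actin-binding protein TAGLN rose by 4.04 ± 0.12. Epithelial genes rose in 14 of 25 cases and fell in 4 (16 and 4 adjusted over the list alone, median 0.30, camera adjusted p = 0.0211, and adjusted p = 0.697 with an estimated correlation), among them the junction proteins CLDN1 (2.66) and CDH1 (1.28).

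Lists of signalling genes were tested in the same way in PC-9 at day 3. NF-kB targets and chemokines rose in 11 of 17 cases and fell in 3 (12 and 3 adjusted over the list alone, median 1.07, camera adjusted p = 0.00431, and adjusted p = 0.248 with an estimated correlation), led by the adhesion molecule ICAM1 (3.48 ± 0.14). YAP/TEAD targets rose in 16 of 21 cases and fell in 3 (16 and 3 adjusted over the list alone, median 0.67, camera adjusted p = 0.000193, and adjusted p = 0.438 with an estimated correlation), with IGFBP3 (2.16) higher and the ectoenzyme NT5E (-2.14) lower. WNT ligands, receptors and targets rose in 16 of 27 cases and fell in 2 (16 and 2 adjusted over the list alone, median 0.43, camera adjusted p = 0.0036, and adjusted p = 0.438 with an estimated correlation), among them the ligands WNT10A (2.25) and WNT11 (1.98). TGF-beta and BMP pathway genes rose in 13 of 28 cases and fell in 4 (15 and 5 adjusted over the list alone, median 0.43, camera adjusted p = 0.0109, and adjusted p = 0.489 with an estimated correlation), among them the ligand TGFB2 (2.12). FOXO-associated genes rose in 11 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.82, camera adjusted p = 0.00147, and adjusted p = 0.248 with an estimated correlation), with the PI3K inhibitor PIK3IP1 at 2.62. Growth factor ligands rose in 18 of 40 cases and fell in 6 (18 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.19), although PDGFB (1.88) and PDGFD (1.94) rose. Receptor tyrosine kinases split into 9 higher and 7 lower of 23 (9 and 7 adjusted over the list alone). Their median was 0.02 and their mean 0.03 while camera pointed down (adjusted p = 0.615). Among them AXL went from 205 to 115 TPM (-0.82) and MET rose by 0.38. EGFR itself, on chromosome 7 (55019021 to 55211628), went from 159 ± 6.04 to 141 ± 4.07 TPM (mean ± SD, -0.17 ± 0.05, adjusted p = 0.0195). The EGFR call did not hold without untreated replicate 1 (adjusted p = 0.0661) or 2 (0.0725), or without day 3 replicate 1 (0.0609) or 3 (0.0671). ERBB3 rose by 0.47 and FGFR1 by 0.74, and neither passed without untreated replicate 3 (adjusted p = 0.0509 for ERBB3 and 0.0571 for FGFR1). IGF1R stood at 0.36 (adjusted p = 0.104, and 0.0173 without day 3 replicate 1), NRG1 at -0.45 (adjusted p = 0.0757, and 0.0345 with median-of-ratios scaling) and BRAF at 0.05 (adjusted p = 0.717). Cyclin D1, CCND1 (-0.46), MYC (-0.83) and TOP2A (-0.89) fell, and the cell cycle inhibitor CDKN1B (0.58), TXNIP (0.74) and MITF (0.45) rose. PDGFRB, MLANA, NGFR and SOX10 were too low in PC-9 to be tested.

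The largest rises in PC-9 at day 3 were the cytokine IL32 (3.84 to 218 TPM, 5.55 ± 0.20; chromosome 16, 3065297 to 3082192), the oxidised-LDL receptor OLR1 (5.96 to 278 TPM, 5.37 ± 0.19) and the keratin KRT17 (13.8 to 467 TPM, 4.98 ± 0.08). The largest falls were the chromatin protein HMGA2 (82.7 to 7.71 TPM, -3.27 ± 0.13), the crosslinking enzyme TGM2 (366 to 39.7 TPM, -3.17 ± 0.06) and the chloride channel ANO1 (118 to 13.7 TPM, -3.03 ± 0.12). The rule for named genes also took RMRP and MIR671, which rose, and the pseudogene MYH16 and SNORA33, which fell. MIR671 did not pass without a filter (adjusted p = 0.0515), nor without day 3 replicate 2 (0.054) or untreated replicates 1 and 2 (0.0655 and 0.0652). SNORA33 lost its call in 7 settings, with adjusted p = 0.106 without a filter and 0.126 without untreated replicate 1. RMRP, MIR671 and SNORA33 are short or non-polyadenylated RNAs that an mRNA library captures poorly. In all, 6806 of 14888 genes tested changed, 4235 up and 2571 down, and 1251 of them by at least 1 on the log2 scale. In 59.5% of the genes tested the 3 treated and 3 untreated libraries did not overlap, against 10% by chance. TPM fixes the total of each library. Scaling by median-of-ratios factors moved the median of all genes from 0.10 to -0.01 and the split to 3538 up and 3761 down, so that 48.5% of the changed genes were higher in place of 62.2%. Of the 32 biology lists 19 passed camera with its preset correlation and 0 with an estimated one. The 19 kept the sign of their median under every scaling, pseudocount and filter tried.

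Most lists that passed camera in PC-9 at day 3 also passed at day 9. The epithelial list did not (adjusted p = 0.0785), while cell cycle inhibitors, which rose in 8 of 13 cases, and nuclear-encoded respiratory chain genes, which fell in 25 of 65, passed at day 9 only (adjusted p = 0.0238 and 0.00437, and 0.481 for both with an estimated correlation). MAPK output genes fell in 19 of 21 cases (19 lower and 1 higher adjusted over the list alone, median -1.14, camera adjusted p = 1.33e-10, and adjusted p = 0.0648 with an estimated correlation), with DUSP6 at -2.65 and SPRY4 at -1.80. S-phase genes fell in 39 of 43 cases (41 adjusted over the list alone, median -0.63) and G2/M genes in 50 of 54 (51 adjusted over the list alone, median -0.51), with camera adjusted p = 2.01e-16 and 4.07e-17, and adjusted p = 0.126 and 0.144 with an estimated correlation. MKI67 (-0.40, adjusted p = 0.00288) and TOP2A (-0.54), which untangles DNA, stayed below untreated. Cholesterol synthesis genes rose in 22 of 24 cases and fell in 1 (23 and 1 adjusted over the list alone, median 1.15, camera adjusted p = 1.57e-13, and adjusted p = 0.0648 with an estimated correlation), with HMGCS1 at 1.80. Antigen presentation genes rose in 14 of 15 cases (14 adjusted over the list alone, median 1.27, camera adjusted p = 4.96e-08, and adjusted p = 0.144 with an estimated correlation), with HLA-B at 3.55 and CD74 at 3.46. Interferon-stimulated genes rose in 24 of 31 cases (25 adjusted over the list alone, median 0.83, camera adjusted p = 9.27e-07, and adjusted p = 0.144 with an estimated correlation).

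YAP/TEAD targets rose in 14 of 21 cases and fell in 2 in PC-9 at day 9 (14 and 2 adjusted over the list alone, median 1.11, camera adjusted p = 1.02e-05, and adjusted p = 0.349 with an estimated correlation), with the matricellular protein CCN1 at 1.70. Mesenchymal genes rose in 13 of 19 cases and fell in 3 (14 and 3 adjusted over the list alone, median 0.71, camera adjusted p = 0.000173, and adjusted p = 0.254 with an estimated correlation), with TAGLN at 4.09, FN1 at 3.23 and SPARC at 2.55. Integrated stress response genes rose in 15 of 21 cases and fell in 2 (15 and 2 adjusted over the list alone, median 0.69, camera adjusted p = 3.31e-05, and adjusted p = 0.349 with an estimated correlation), including asparagine synthetase, ASNS (1.86), and NUPR1 (0.426 to 37.7 TPM, 4.78 ± 0.21). Ribosome biogenesis genes fell in 30 of 30 cases (30 adjusted over the list alone, median -0.64, camera adjusted p = 3.16e-15, and adjusted p = 0.0648 with an estimated correlation). Ribosomal protein genes fell in 59 of 75 cases (63 adjusted over the list alone, median -0.26, camera adjusted p = 2.24e-16, and adjusted p = 0.144 with an estimated correlation), while mitochondrial-encoded genes rose in 9 of 13 (10 adjusted over the list alone, median 0.80). Of the receptors, FGFR1 went from 9.63 to 25.6 TPM (1.33 ± 0.20, adjusted p = 0.000814), and ERBB3 (0.70), IGF1R (0.80) and MET (0.48) rose, while EGFR (-0.30 ± 0.05) and AXL (-0.50) fell. NRG1, the ligand of ERBB3, stood at 0.10 (adjusted p = 0.695). BRAF fell by 0.31 (adjusted p = 0.0296), and lost its call in 7 settings. These were no filter (adjusted p = 0.0531), a replicate block (0.0529), mitochondrial-encoded genes left out of TPM (0.057), and leaving out day 9 replicate 1 or 3 (0.0833 and 0.0921) or untreated replicate 1 or 2 (0.0922 and 0.0775). IGFBP5, a binding protein of insulin-like growth factors on chromosome 2 (216672105 to 216695525), went from 0.17 to 26.6 TPM (4.56 ± 0.09, adjusted p = 1.94e-08). OLR1 (5.56), KRT17 (4.97) and IL32 (4.77) again led the rises, and ANO1 (-3.82), MYH16 (-3.36), the adhesion molecule CEACAM6 (75.3 to 6.56 TPM, -3.34 ± 0.06), CAPN8 (-3.21) and HMGA2 (-3.11) led the falls. In all, 6597 genes changed, 3636 up and 2961 down, and in 53.9% of the genes tested the groups did not overlap, against 10% by chance. Rescaling TPM without the mitochondrial-encoded genes raised the share of changed genes that were higher from 55.1% to 66.2%. With median-of-ratios factors 3336 rose and 3822 fell (46.6% higher), and without day 9 replicate 2 the split was 3198 and 3417 (48.3% higher), so the balance depended on the scaling and on 1 library. Of the 32 lists 20 passed camera and 0 with an estimated correlation.

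Between day 3 and day 9 PC-9 cells raised part of the cycling genes and most mitochondrial transcripts. G2/M genes rose in 17 of 54 cases and fell in none (30 adjusted over the list alone, median 0.23, camera adjusted p = 3.52e-16, and adjusted p = 0.589 with an estimated correlation), among them the chromatin protein HMGB2 (0.41) and NUSAP1 (0.38). TOP2A rose by 0.34 (adjusted p = 0.0121, and 0.0506 without day 3 replicate 2), and MKI67 stood at 0.15 (adjusted p = 0.263, and 0.0262 with mitochondrial-encoded genes left out of TPM). S-phase genes rose in 6 of 43 cases (9 adjusted over the list alone, median 0.13, camera adjusted p = 2.01e-06, and adjusted p = 0.592 with an estimated correlation), and MAPK output genes in 4 of 21 (7 higher and 1 lower adjusted over the list alone, median 0.15, camera adjusted p = 0.000235, and adjusted p = 0.589 with an estimated correlation), with MYC at 0.40. YAP/TEAD targets rose in 6 of 21 cases and fell in 2 (11 and 3 adjusted over the list alone, median 0.21, camera adjusted p = 4.99e-05, and adjusted p = 0.598 with an estimated correlation), with CCN2 going from 15.2 to 30.5 TPM (0.96) and ANKRD1 at 0.84. With TPM rescaled without mitochondrial-encoded genes, 35 G2/M genes rose (median 0.36), 18 of S phase, 9 of MAPK output and 12 of YAP/TEAD. Without a filter on expression these numbers were 8, 3, 2 and 4. Mitochondrial-encoded genes rose in 11 of 13 cases (13 adjusted over the list alone, median 1.31, camera adjusted p = 1.64e-24, and adjusted p = 0.0245 with an estimated correlation), with MT-ND1 going from 1290 to 3570 TPM (1.47 ± 0.07). They took 6.51 to 7.63% of TPM in the day 3 libraries and 16.2, 11.4 and 17.0% in the day 9 libraries.

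**Figure D1:**
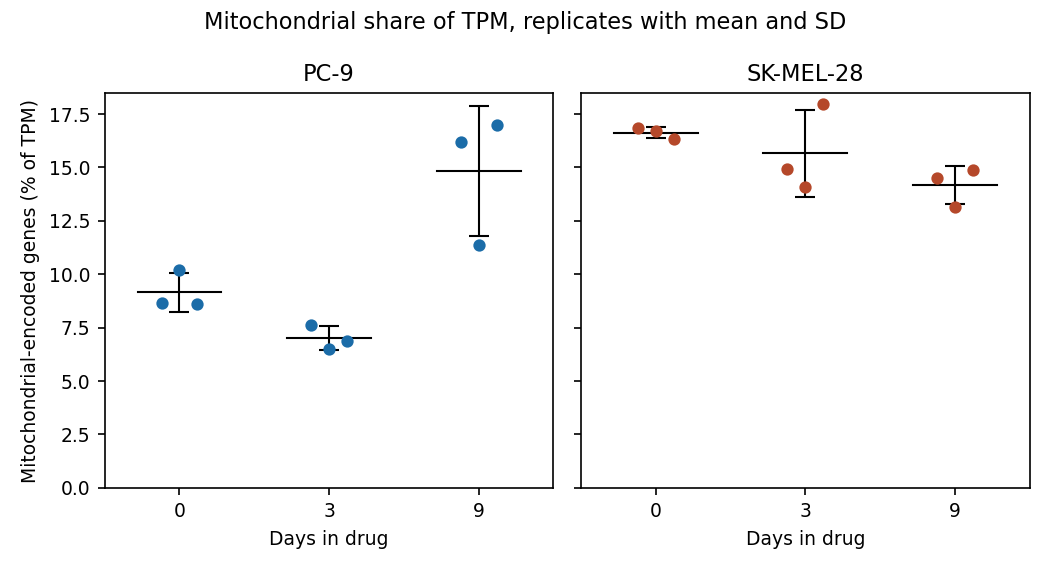
Share of TPM taken by mitochondrial-encoded genes (%, vertical axis) against days in drug (horizontal axis) in PC-9 (left) and SK-MEL-28 (right). Points are libraries, long lines are group means and error bars are SD; PC-9 day 9 libraries lie between 11.36 and 17%, above all day 3 libraries (6.51 to 7.63%).

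The list medians of the falling groups were small in this comparison. Ribosomal protein genes fell in 29 of 75 cases (39 adjusted over the list alone, median -0.13, camera adjusted p = 1.69e-10, and adjusted p = 0.592 with an estimated correlation). With TPM rescaled without mitochondrial-encoded genes, 2 fell and 1 rose and the median was -0.01. Nuclear-encoded respiratory chain genes fell in 14 of 65 cases and rose in 1 (22 and 1 adjusted over the list alone, median -0.14, camera adjusted p = 0.000192, and adjusted p = 0.598 with an estimated correlation), and after the same rescaling 4 fell and 6 rose. Lysosome genes fell in 8 of 30 cases (9 adjusted over the list alone, median -0.16, camera adjusted p = 0.00182, and adjusted p = 0.633 with an estimated correlation), and after it 4 fell and 1 rose. Without a filter, 8 ribosomal protein, 9 respiratory chain and 6 lysosome genes fell. The largest rises included IGFBP5 (4.42 to 26.6 TPM, 2.35 ± 0.09, adjusted p = 8.8e-06), the prostacyclin synthase PTGIS (1.75 ± 0.15) and NUPR1 (1.62 ± 0.21, which did not pass with a pseudocount of 0.1, at adjusted p = 0.0875). The largest falls included SPANXB1 (-1.45 ± 0.08), CEACAM6 (-1.40 ± 0.06) and the calcium-binding protein S100A4 (284 to 110 TPM, -1.37 ± 0.08, adjusted p = 7.01e-05; chromosome 1, 153543613 to 153550136). The rule also took the pseudogene MTATP6P1 (1.49), SYTL4 (-1.45 ± 0.35, adjusted p = 0.041, but 0.0963 without a filter, 0.0668 with a replicate block and up to 0.115 with 1 library left out), and the short RNAs RNU6-945P, listed at 0 at day 3, and MIR573, listed at 0 at day 9. In all, 1274 of 14888 genes changed, 346 up and 928 down. Rescaled without mitochondrial-encoded genes the split was 1159 up and 436 down, and with median-of-ratios factors 709 up and 849 down. The count ranged from 539 to 2279 when 1 library was left out, with 2279 without day 9 replicate 2, 691 without day 9 replicate 1, 654 without day 9 replicate 3, and 570, 581 and 539 without day 3 replicates 1, 2 and 3. Groups did not overlap in 29.1% of genes, against 10% by chance.

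In SK-MEL-28 cells after 3 days of dabrafenib, MAPK output and the cell cycle fell further than in PC-9. All 20 MAPK output genes tested fell (20 adjusted over the list alone, median -3.23, camera adjusted p = 2.9e-12, and adjusted p = 0.0366 with an estimated correlation). DUSP6 went from 66.8 to 1.25 TPM (-4.93 ± 0.14), SPRY4 from 35.1 to 0.0444 TPM (-5.11 ± 0.08) and cyclin D1, CCND1, from 336 to 50.4 TPM (-2.72 ± 0.05). All 43 S-phase genes (43 adjusted over the list alone, median -2.26) and 53 of 54 G2/M genes (54 adjusted over the list alone, median -3.08) fell, with camera adjusted p = 1.64e-17 and 3.02e-21, and adjusted p = 0.00518 for both with an estimated correlation. MKI67 went from 51.8 to 2.85 TPM (-3.77 ± 0.11), TOP2A fell by 3.96, and the nucleotide reductase subunit RRM2 fell by 4.62. Pigment cell genes rose in 17 of 20 cases and fell in 3 (17 and 3 adjusted over the list alone, median 0.78, camera adjusted p = 1.09e-05, and adjusted p = 0.331 with an estimated correlation). The melanin synthesis enzyme TYRP1, on chromosome 9 (12685439 to 12710290), went from 110 to 3420 TPM (4.95 ± 0.03, adjusted p = 5.35e-11), DCT from 232 to 2150 TPM (3.20 ± 0.03) and the melanosome protein PMEL from 6310 to 18400 TPM (1.55). The lineage factor MITF, on chromosome 3 (69739435 to 69968337), went from 245 to 313 TPM (0.35 ± 0.05), and MLANA from 1770 ± 26.9 to 3220 ± 106 TPM (0.86 ± 0.04).

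Metabolic and stress genes also moved in SK-MEL-28 at day 3. Glycolysis genes fell in 16 of 19 cases and rose in 1 (16 and 1 adjusted over the list alone, median -1.39, camera adjusted p = 6.05e-07, and adjusted p = 0.182 with an estimated correlation), with pyruvate kinase, PKM, going from 2230 to 464 TPM (-2.26 ± 0.03) and GAPDH at -1.95. Ribosome biogenesis genes fell in 29 of 30 cases (29 adjusted over the list alone, median -1.12, camera adjusted p = 7.41e-11, and adjusted p = 0.0824 with an estimated correlation), while ribosomal protein genes rose in 48 of 75 and fell in 7 (48 and 7 adjusted over the list alone, median 0.15, camera adjusted p = 1.09e-05, and adjusted p = 0.51 with an estimated correlation). Integrated stress response genes rose in 16 of 22 cases and fell in 3 (16 and 3 adjusted over the list alone, median 1.09, camera adjusted p = 1.2e-05, and adjusted p = 0.0824 with an estimated correlation), among them ATF4 (1.65) and NUPR1 (14.4 to 202 TPM, 3.72). Unfolded protein response genes fell in 13 of 17 cases and rose in 2 (13 and 2 adjusted over the list alone, median -0.73, camera adjusted p = 0.000357, and adjusted p = 0.15 with an estimated correlation), including the chaperone HSP90B1 (-1.42). NF-kB targets and chemokines fell in 10 of 14 cases and rose in 1 (10 and 2 adjusted over the list alone, median -1.39, camera adjusted p = 0.003, and adjusted p = 0.223 with an estimated correlation), with CXCL8 at -4.32 and ICAM1 at -2.22. Mesenchymal genes split into 7 higher and 7 lower of 20 (camera adjusted p = 0.607), with the matrix protein tenascin C, TNC, going from 791 to 16.4 TPM (-5.51). YAP/TEAD targets split into 6 higher and 7 lower of 19, with a median of 0.08 while camera pointed down (adjusted p = 0.85). NGFR, a marker of neural-crest-like melanoma cells, went from 5.33 to 0.799 TPM (-1.82 ± 0.10). ERBB3 went from 58.9 to 111 TPM (0.90), and the ligand NRG1 fell by 1.57. MET rose by 0.17 (adjusted p = 0.0396), a call lost in several settings, with adjusted p = 0.126 without untreated replicate 1, 0.0669 without untreated replicate 2, and 0.115 and 0.0809 without day 3 replicates 1 and 3. AXL stood at -0.18 and FGFR1 at -0.37, and neither passed. MYC fell by 2.48 and IGF1R by 0.67, while SOX10 (0.35), CDKN1B (0.86) and TXNIP (1.44) rose, and BRAF stood at 0.30 (adjusted p = 0.132, and 0.0435 without untreated replicate 3). EGFR and PDGFRB were too low in SK-MEL-28 to be tested.

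The largest rises in SK-MEL-28 at day 3 were the non-coding RNA LINC01933 (0.071 to 47.8 TPM, 5.51 ± 0.20), PRUNE2 (1.74 to 97.4 TPM, 5.17 ± 0.08) and the secreted serpin SERPINF1 (12.6 to 449 TPM, 5.09 ± 0.17). The largest falls were MYEOV (341 TPM in untreated cells, -7.05 ± 0.44; chromosome 11, 69294138 to 69367726), the peptide hormone UCN2 (96.1 to 0.263 TPM, -6.27 ± 0.14), the antisense RNA HECW2-AS1 (-5.77 ± 0.12) and the gap junction protein GJB1 (-5.64 ± 0.11). The rule also took SEPTIN14P22 and MIR4800, listed at 0 in untreated cells, and the pseudogene TMSB4XP6, which fell. In all, 9606 of 14729 genes tested changed, 4732 up and 4874 down, and 3050 of them by at least 1 on the log2 scale. Groups did not overlap in 69.7% of genes, against 10% by chance. Of the 32 lists 14 passed camera, 5 up and 9 down. With an estimated correlation 3 remained past the threshold, MAPK output, S phase and G2/M.

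At day 9 most pigment cell genes of SK-MEL-28 were below untreated, and most mesenchymal and YAP/TEAD genes were above it. Pigment cell genes fell in 17 of 20 cases and rose in 3 (17 and 3 adjusted over the list alone, median -1.74, camera adjusted p = 3.69e-07, and adjusted p = 0.186 with an estimated correlation). MITF went from 245 in untreated cells to 46.4 TPM (-2.38 ± 0.05), MLANA from 1770 to 546 ± 30.1 TPM (-1.70 ± 0.04), PMEL from 6310 to 1830 TPM (-1.79), while TYRP1, at 110 TPM in untreated cells, stood at 290 TPM, and the neural crest factor SOX10, on chromosome 22 (37970686 to 37987422), from 204 to 122 TPM (-0.74 ± 0.06). Mesenchymal genes rose in 17 of 20 cases and fell in 3 (17 and 3 adjusted over the list alone, median 2.10, camera adjusted p = 5.41e-08, and adjusted p = 0.0425 with an estimated correlation). The collagen COL1A1, on chromosome 17 (50183289 to 50201632), went from 0.163 to 65.3 TPM (5.83 ± 0.09), COL5A1 rose by 5.68, and the matrix protein SPARC went from 2300 to 14100 TPM (2.61 ± 0.03). YAP/TEAD targets rose in 18 of 19 cases and fell in 1 (18 and 1 adjusted over the list alone, median 1.75, camera adjusted p = 1.15e-08, and adjusted p = 0.0122 with an estimated correlation). CCN1, on chromosome 1 (85580761 to 85583962), went from 3.63 to 318 TPM (6.11 ± 0.05, adjusted p = 1.01e-10) and IGFBP3 from 13.1 to 568 TPM (5.33). Of the 12 neural crest and dedifferentiated melanoma genes 7 rose and 4 fell (7 and 4 adjusted over the list alone, median 1.13, mean 0.63), and the list did not pass camera (adjusted p = 0.182). NGFR went from 5.33 to 27.9 TPM (2.19 ± 0.10), and AXL from 0.225 to 2.3 TPM (1.43 ± 0.10). Of 3 fibroblast and endothelial markers tested, the collagens COL1A1 and COL3A1 rose, COL3A1 from libraries listed at 0 to 2.64 TPM, while LUM went from 21.3 to 18.0 TPM (-0.24, adjusted p = 0.0569), and the list had camera adjusted p = 0.162.

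**Figure D2:**
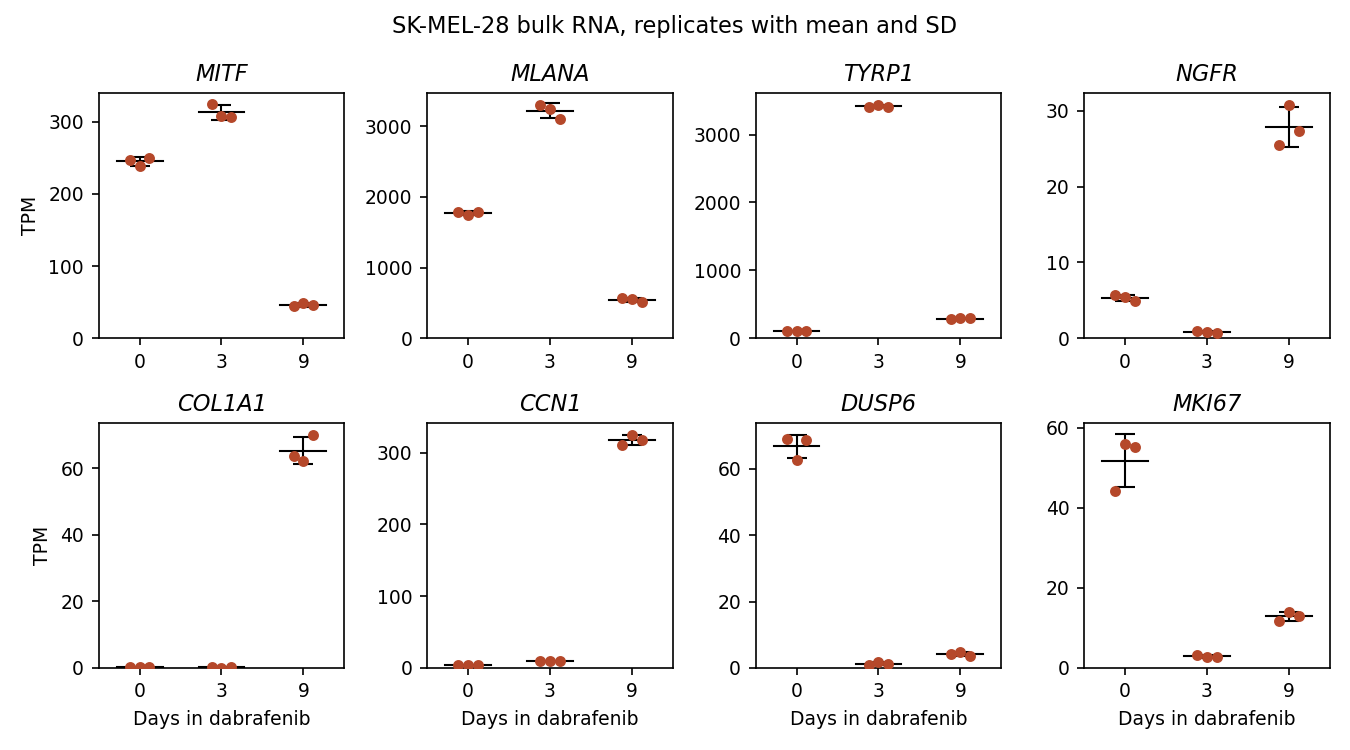
TPM (vertical axes, linear, starting at 0) of 8 genes in SK-MEL-28 bulk RNA against days in dabrafenib (horizontal axes). Points are the 3 libraries of each group, long lines their mean and error bars SD; MITF went from 245 to 313 and 46.4 TPM, and NGFR from 5.33 to 0.799 and 27.9 TPM.

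Lists of ligands, receptors and the TGF-beta and BMP pathway were higher in SK-MEL-28 at day 9, and none of these 3 passed with an estimated correlation. Growth factor ligands rose in 24 of 35 cases and fell in 9 (24 and 9 adjusted over the list alone, median 0.84, camera adjusted p = 0.00083, and adjusted p = 0.0949 with an estimated correlation), among them the neurotrophin BDNF (2.42) and the EGF-family ligand HBEGF (1.83). NRG1 rose by 1.39 ± 0.20. Receptor tyrosine kinases rose in 13 of 24 cases and fell in 5 (13 and 5 adjusted over the list alone, median 0.49, camera adjusted p = 0.027, and adjusted p = 0.261 with an estimated correlation), with the neurotrophin receptor NTRK2 at 3.41, MET going from 20.4 to 53.1 TPM (1.34 ± 0.06), FGFR1 from 6.03 to 16.8 TPM (1.36 ± 0.25) and ERBB3 falling by 0.70. TGF-beta and BMP pathway genes rose in 20 of 30 cases and fell in 5 (21 and 5 adjusted over the list alone, median 0.88, camera adjusted p = 0.000768, and adjusted p = 0.186 with an estimated correlation), among them the ligand BMP2 (2.71). FOXO-associated genes rose in 12 of 16 cases and fell in 3 (12 and 3 adjusted over the list alone, median 0.73, camera adjusted p = 0.000705, and adjusted p = 0.0425 with an estimated correlation), and integrated stress response genes rose in 20 of 22 and fell in 1 (20 and 1 adjusted over the list alone, median 1.49, camera adjusted p = 3.98e-11, and adjusted p = 0.0184 with an estimated correlation), with ASNS going from 42.9 to 358 TPM (3.03). MAPK output fell in 18 of 20 genes (18 lower and 1 higher adjusted over the list alone, median -1.99, camera adjusted p = 1.54e-08, and adjusted p = 0.0425 with an estimated correlation), with DUSP6 at -3.72 and SPRY4 at -4.47. S-phase genes fell in 42 of 43 cases (42 adjusted over the list alone, median -1.23) and G2/M genes in 53 of 54 with 1 higher (53 and 1 adjusted over the list alone, median -1.23), with camera adjusted p = 4.28e-12 and 2.65e-13, and adjusted p = 0.0122 for both with an estimated correlation. MKI67 stood at 12.9 TPM (-1.92 ± 0.11). Antigen presentation genes fell in 15 of 21 cases and rose in 1 (18 and 1 adjusted over the list alone, median -1.16, camera adjusted p = 8.53e-05, and adjusted p = 0.128 with an estimated correlation). CD74 went from 47.1 to 1.79 TPM (-4.12). Cholesterol synthesis genes fell in 18 of 24 cases and rose in 2 (18 and 2 adjusted over the list alone, median -0.63, camera adjusted p = 0.00018, and adjusted p = 0.107 with an estimated correlation), with FDFT1 at -1.68. The largest rises were the small heat shock protein CRYAB (0.528 to 578 TPM, 8.57 ± 0.14, adjusted p = 1.29e-09; chromosome 11, 111908565 to 111923722), the natriuretic peptide NPPB (7.45 ± 0.09), LINC00968 (7.08 ± 0.14), EDIL3 (6.77 ± 0.22) and CPA4 (6.50 ± 0.18). The largest falls were the phospholipase PLA1A (279 to 0.815 TPM, -7.27 ± 0.05), GJB1 (-6.76 ± 0.11), UCN2 (-6.34), LPXN (-5.77 ± 0.27) and MYEOV (-5.64). In all, 9209 genes changed, 4252 up and 4957 down, 2728 of them by at least 1 on the log2 scale. Groups did not overlap in 67.6% of genes, against 10% by chance. Of the 32 lists 18 passed camera, and 7 with an estimated correlation.

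Between day 3 and day 9 pigment genes fell in the melanoma cells while mesenchymal, neural crest and cycling genes rose. Pigment cell genes fell in 19 of 20 cases (19 adjusted over the list alone, median -2.76, camera adjusted p = 1.02e-14, and adjusted p = 0.134 with an estimated correlation), with DCT going from 2150 to 79.9 TPM (-4.73 ± 0.03, adjusted p = 4.2e-11), TYRP1 from 3420 to 290 TPM (-3.56), MITF at -2.73 and SOX10 at -1.09. Mesenchymal genes rose in 13 of 20 cases and fell in 6 (14 and 6 adjusted over the list alone, median 2.76, camera adjusted p = 0.000127, and adjusted p = 0.134 with an estimated correlation), and YAP/TEAD targets rose in 17 of 19 and fell in 1 (17 and 1 adjusted over the list alone, median 1.66, camera adjusted p = 4.29e-09, and adjusted p = 0.0119 with an estimated correlation), with IGFBP3 going from 7.1 to 568 TPM (6.14 ± 0.06). Neural crest and dedifferentiated melanoma genes rose in 9 of 12 cases (9 adjusted over the list alone, median 1.47, camera adjusted p = 0.00021, and adjusted p = 0.134 with an estimated correlation), with NGFR going from 0.799 to 27.9 TPM, the collagen crosslinker LOXL2 at 5.99 and TNC at 4.35. G2/M genes rose in 50 of 54 cases and fell in 1 (50 and 1 adjusted over the list alone, median 1.82, camera adjusted p = 3.58e-16, and adjusted p = 0.0119 with an estimated correlation), and S-phase genes in 39 of 43 (39 adjusted over the list alone, median 1.10, camera adjusted p = 2.75e-11, and adjusted p = 0.0122 with an estimated correlation). MKI67 rose from 2.85 to 12.9 TPM (1.85 ± 0.11) and TOP2A by 2.52. MAPK output rose in 16 of 20 genes and fell in 2 (16 and 2 adjusted over the list alone, median 1.05, camera adjusted p = 5.67e-05, and adjusted p = 0.134 with an estimated correlation), with SPRY2 at 3.06, IER3 at 3.32 and DUSP6 going from 1.25 to 4.18 TPM (1.21). Glycolysis genes rose in 16 of 19 cases and fell in 2 (16 and 2 adjusted over the list alone, camera adjusted p = 3.01e-08, and adjusted p = 0.134 with an estimated correlation), with PKM going from 464 to 1630 TPM (1.81). Ribosomal protein genes fell in 70 of 75 cases (71 adjusted over the list alone, median -0.43, camera adjusted p = 5.16e-19, and adjusted p = 0.153 with an estimated correlation). Genes of the immediate early and dissociation stress response rose in 10 of 14 cases (11 adjusted over the list alone, median 0.85). The largest rises included NPPB (6.94 ± 0.09), IGFBP3, CPA4 (6.07) and LOXL2. The largest falls were CSAG2, listed at 0 at day 9, PLA1A (-4.75), DCT, LINC01933 (-4.40) and STK32A (-4.24). In all, 8816 genes changed, 4386 up and 4430 down, 2429 of them by at least 1 on the log2 scale. Groups did not overlap in 66.1% of genes, against 10% by chance. Of the 32 lists 16 passed camera, and 3 with an estimated correlation.

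**Figure D3:**
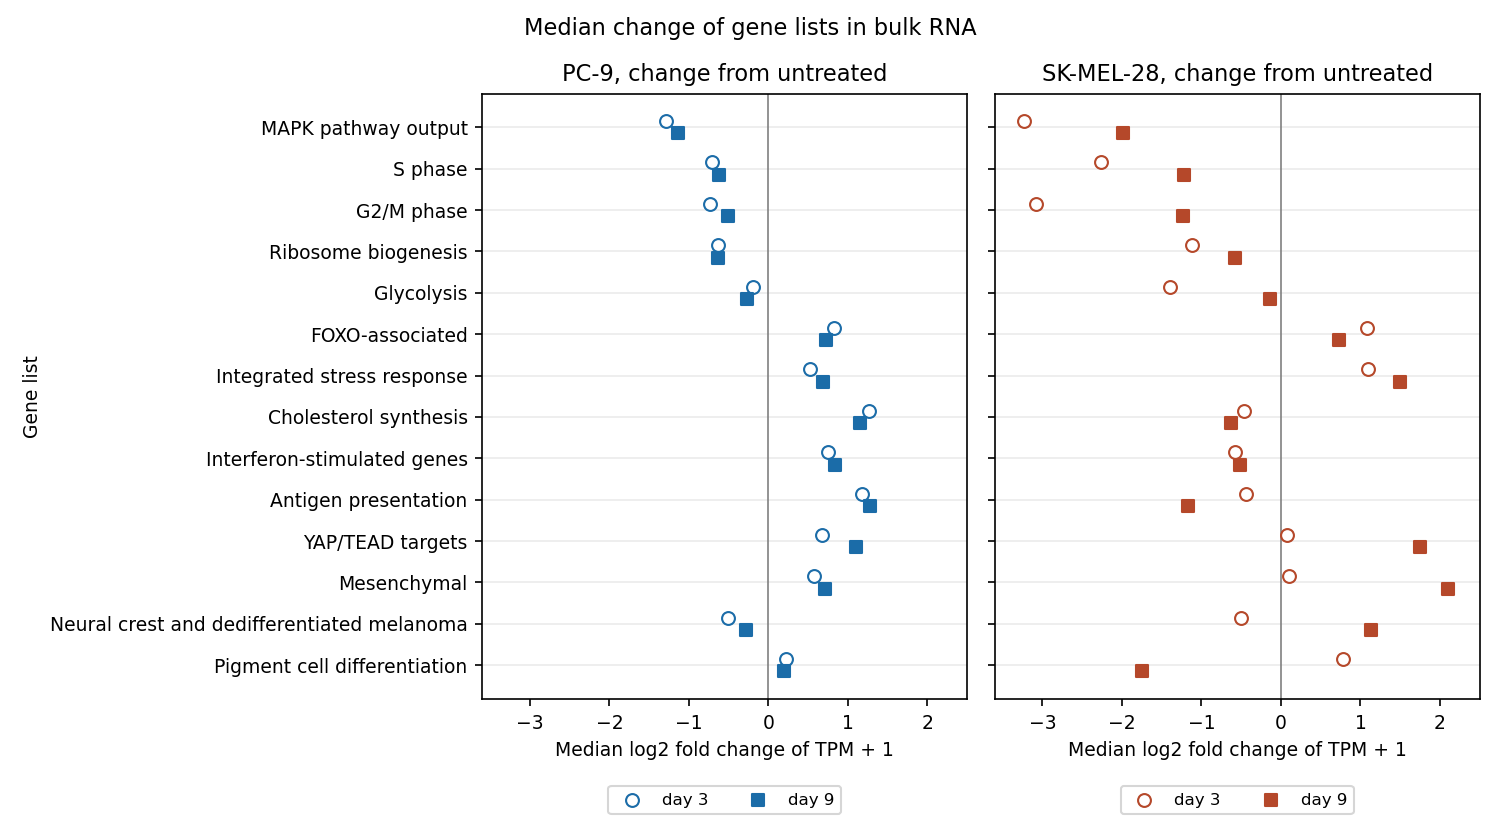
Median log2 fold change of TPM + 1 from untreated (horizontal axis) of 14 gene lists (vertical axis) in PC-9 (left) and SK-MEL-28 (right). Open circles are day 3 and filled squares day 9; in SK-MEL-28 the pigment list went from 0.78 to -1.74, while cholesterol synthesis stood at 1.27 and 1.15 in PC-9.

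The lines were compared directly by the difference of their responses, SK-MEL-28 minus PC-9, over 17301 genes. At day 3 the fall of cycling genes was larger in SK-MEL-28. G2/M genes were lower in 51 of 54 cases (51 adjusted over the list alone, median difference -2.36, camera adjusted p = 9.21e-22, and 0.013 with an estimated correlation), with MKI67 at -3.23 and TOP2A at -3.07. MAPK output was lower in 19 of 21 cases and higher in 2 (19 and 2 adjusted over the list alone, median -2.25, camera adjusted p = 3.93e-09, and adjusted p = 0.013 with an estimated correlation). Cholesterol synthesis genes were lower in 22 of 24 cases and higher in 1 (22 and 1 adjusted over the list alone, median -1.55, camera adjusted p = 2.92e-11, and adjusted p = 0.013 with an estimated correlation), with HMGCS1 at -2.85. Antigen presentation genes were lower in 17 of 21 cases and higher in 1 (17 and 1 adjusted over the list alone, median -1.34, camera adjusted p = 9.53e-07, and adjusted p = 0.0354 with an estimated correlation), with CD74 at -4.45. Interferon-stimulated genes were lower in 26 of 33 cases and higher in 1 (26 and 1 adjusted over the list alone, median -1.15), and NF-kB targets in 15 of 20 with 1 higher (15 and 1 adjusted over the list alone, median -1.97), with adjusted p = 0.0354 and 0.0315 with an estimated correlation. Pigment cell genes were higher in 14 of 20 cases and lower in 4 (14 and 4 adjusted over the list alone, median 0.89, camera adjusted p = 1.77e-06, and adjusted p = 0.105 with an estimated correlation), though only 8 of them were high enough to be tested in PC-9 alone. AXL stood at 0.64, and at -0.11 with a pseudocount of 0.1, the gene having 0.225 TPM in untreated SK-MEL-28 cells. In all, 8387 genes differed at day 3, 3053 higher and 5334 lower. Median-of-ratios scaling moved the median of all differences from -0.11 to 0.00 and the split to 4044 and 4608, so that 46.7% were higher in place of 36.4%.

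At day 9 the lines also differed in mesenchymal, YAP/TEAD and immune genes. YAP/TEAD targets were higher in SK-MEL-28 in 14 of 22 cases and lower in 4 (15 and 4 adjusted over the list alone, median 0.78, camera adjusted p = 1.24e-06, and adjusted p = 0.0654 with an estimated correlation), with CCN1 at 4.41. Mesenchymal genes were higher in 17 of 23 cases and lower in 4 (17 and 4 adjusted over the list alone, median 0.75, camera adjusted p = 9.73e-06, and adjusted p = 0.0842 with an estimated correlation), with COL1A1 at 4.99. Antigen presentation genes were lower in all 21 cases (21 adjusted over the list alone, median -1.79, camera adjusted p = 3.69e-12, and adjusted p = 0.011 with an estimated correlation), with B2M at -1.92. Cholesterol synthesis genes were lower in 22 of 24 cases and higher in 2 (22 and 2 adjusted over the list alone, median -1.59, camera adjusted p = 3.69e-12, and adjusted p = 0.011 with an estimated correlation), with MSMO1 at -3.40. Pigment cell genes were lower in 18 of 20 cases and higher in 2 (18 and 2 adjusted over the list alone, median -1.54, camera adjusted p = 3.12e-08, and adjusted p = 0.0654 with an estimated correlation), with MITF at -2.83. Only 8 of these genes were high enough to be tested in PC-9 alone, so for the others the difference is mainly the SK-MEL-28 change. The MLANA difference did not pass with a pseudocount of 0.1 (adjusted p = 0.405). AXL (1.93), MET (0.86) and NRG1 (1.30) were higher and ERBB3 (-1.40) lower, while FGFR1 (0.02, adjusted p = 0.971) and IGF1R (-0.27, adjusted p = 0.275) did not differ past the threshold. In all, 8000 genes differed, 3372 higher and 4628 lower. The split was 4235 and 4184 with median-of-ratios factors (50.3% higher), and 2817 and 5820 with TPM rescaled without mitochondrial-encoded genes. Of the 32 lists 16 passed camera at day 3 and 18 at day 9, and 8 and 2 with an estimated correlation.

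Part of the response was shared by the lines. Of 12592 genes tested in both, 1516 rose in both at day 9, where independent lists would share 862.9, and 1647 fell in both, where they would share 895.3. Another 998 moved in opposite directions, and the changes correlated across genes with Pearson r = 0.322 and Spearman rho = 0.338. Genes are not independent replicates, so these values describe the lists. At day 3, a comparison chosen after seeing the data, 1808 rose in both (1118.7 for independent lists), 1651 fell in both (781.1) and 1039 moved apart (r = 0.377). Leaving out replicate 1 of every group gave 1770 shared genes at day 9 in place of 3163, and 2141 at day 3 in place of 3459. MAPK output, S-phase and G2/M genes such as DUSP6, TYMS and BUB1 fell in PC-9 and these lists also fell in SK-MEL-28. Within PC-9, 3049 genes rose and 2114 fell at both days, 41 moved in opposite directions, and r was 0.848. Independent lists would share 1034.3 and 511.3. Without replicate 1 of every group the shared genes within PC-9 numbered 3138 in place of 5163. Within SK-MEL-28, 2579 rose and 3292 fell at both days, where independent lists would share 1366 and 1640.3, 1216 moved in opposite directions, and r was 0.563. Both days were compared with the same untreated libraries. In groups simulated without any change, sharing them gave r = 0.498 in PC-9 and 0.489 in SK-MEL-28, with 0 genes shared. The covariance of the changes was 0.343 in PC-9 and 0.524 in SK-MEL-28, against 0.0343 and 0.0319 simulated. These values argue against the shared controls as the main source of the excess, while a smaller part is not excluded.

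In single cells the share with high G2/M counts was lower at each later time. Cells were thinned to 5000 UMIs, and a cell with at least 25 UMIs of the 54 G2/M genes was counted as G2/M-high. In PC-9 the G2/M-high share was 46.3% of untreated cells (1097 of 2369; exact 95% interval 44.3 to 48.3), 22.0% at 24 h (20.04 to 24.07), 7.32% at 48 h (6.2 to 8.58) and 5.42% at 72 h (94 of 1735; 4.4 to 6.59). In SK-MEL-28 it was 28.7% of untreated cells (518 of 1808; 26.6 to 30.8), 2.65% at 24 h (2.0 to 3.43), 1.05% at 48 h (0.7 to 1.51) and 0.72% at 72 h (23 of 3173; 0.46 to 1.09). The untreated SK-MEL-28 share was 27.16% (418 of 1539) without barcodes under 2% mitochondrial, some of which may not be whole cells. Intervals cover counting error only, since there was 1 library per time and no test was made. Those of 48 and 72 h overlapped in both lines. In untreated PC-9, 790 cells lay within 5 UMIs of the minimum, so the level of that share depends on it. A minimum of 15 UMIs gave 84.0% and one of 40 gave 14.0%, and with either the share at 72 h stayed below the untreated share (9.86% and 2.02%). With 40 UMIs the PC-9 share at 24 h was 11.75% (10.24 to 13.39), and its interval overlapped the untreated one (12.6 to 15.43). Free RNA was not separated from cells, and phase was not called. MLANA, an abundant melanocyte transcript, had a UMI in 0 of the PC-9 cells, while the pigment cell gene PMEL had one in 3.99 to 16.31% of them. Such markers of the other line do not measure free RNA from a library's own cells.

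**Figure D4:**
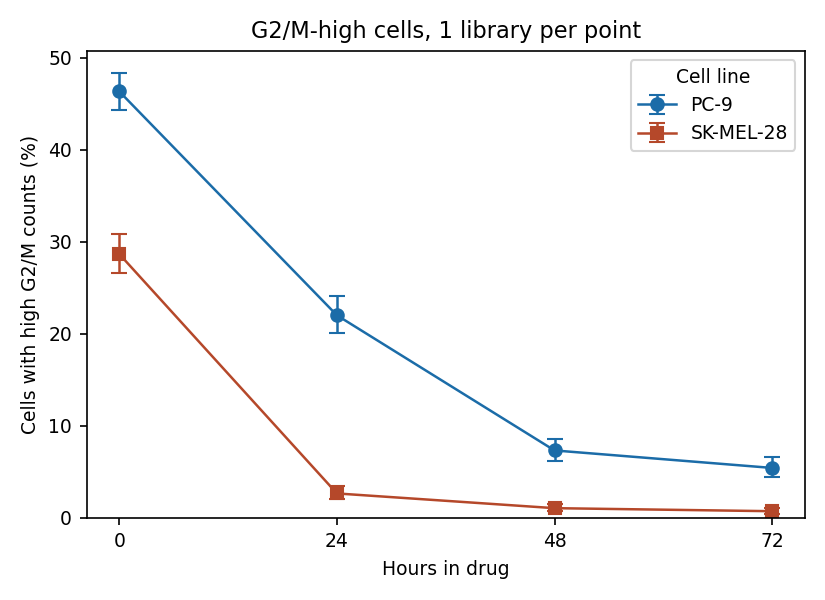
Share of cells with high G2/M counts (%, vertical axis) against hours in drug (horizontal axis) for PC-9 and SK-MEL-28, 1 library per point. Error bars are exact 95% binomial intervals and cover counting error only; the share went from 46.31 to 5.42% in PC-9 and from 28.65 to 0.72% in SK-MEL-28.

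Summed over cells, some gene lists had moved at 24 h, while others lay where random lists lie, such as ribosomal proteins in PC-9 (-0.03, percentile 49.85). The values that follow are log2 ratios of CPM to the untreated library, with the percentile of each list's median among 10000 random lists of matched expression. In PC-9 the median of MAPK output was -1.52 at 24 h, -1.42 at 48 h and -0.90 at 72 h (19 of 21 genes below untreated at 72 h, percentile 0), and that of G2/M genes was -0.62, -1.92 and -2.02 (54 of 54 below, percentile 0). Cholesterol synthesis stood at 2.00, 2.19 and 1.59 (23 of 24 above at 72 h, percentile 100), and antigen presentation at 1.36, 1.60 and 1.47 (15 of 16 above, percentile 100). Interferon-stimulated genes stood at 0.96, 0.95 and 0.93 (23 above and 3 below at 72 h, percentile 99.99, with random lists at 0.25), and mesenchymal genes at 1.29 at 72 h (14 above, 2 below; percentile 100). In SK-MEL-28 the G2/M median was -2.15, -2.74 and -2.98 (54 of 54 below at 72 h, percentile 0), and that of MAPK output was -2.47 at 72 h (20 of 20 below). Pigment cell genes stood at 1.02, 1.07 and 1.04 (17 above and 3 below at each time, percentile 100), glycolysis at -1.62 at 72 h (18 of 19 below, percentile 0), neural crest and dedifferentiated melanoma genes at -1.46 (8 below, 2 above; percentile 0.02) and NF-kB targets at -1.20 (12 below, 1 above; percentile 0.01). Scaling the SK-MEL-28 sums by TMM factors raised treated over untreated by 0.31 on the log2 scale at 72 h, and the list medians, with their pseudocount, moved by a median of 0.28 and at most 0.54. At that time the medians of the epithelial, mesenchymal, cholesterol synthesis, BCL2 family and histone methylation lists changed sign with it, so no direction is given for them in these sums. Leaving out barcodes under 2% mitochondrial moved the SK-MEL-28 list medians at 72 h by at most 0.42, that of the neural crest list to -1.04.

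**Figure D5:**
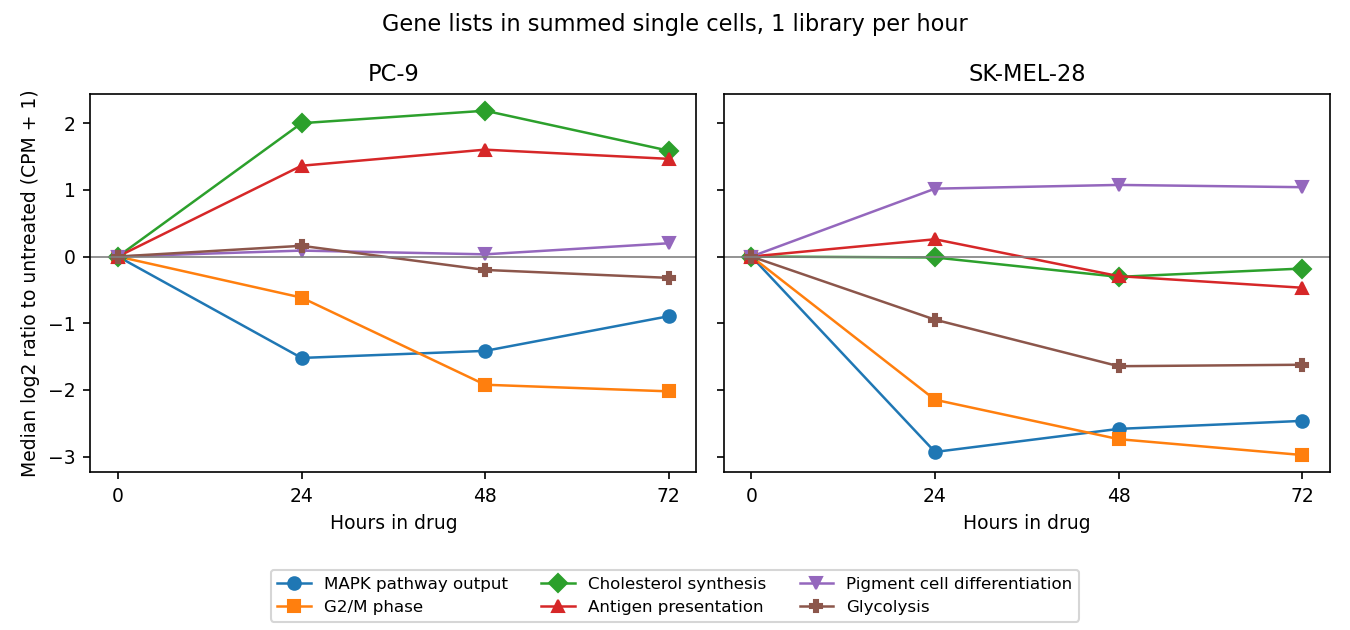
Median log2 ratio of CPM + 1 to the untreated library (vertical axis) against hours in drug (horizontal axis) for 6 gene lists, from counts summed over the cells of 1 library per time, PC-9 left and SK-MEL-28 right. G2/M genes reached -2.02 in PC-9 and -2.98 in SK-MEL-28 at 72 h; the SK-MEL-28 cholesterol synthesis line lies near 0 and its sign at 72 h depends on the scaling.

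Among single genes at 72 h, compared without a pseudocount, CDKN2B had the highest ratio in PC-9 (0.683 to 52.6 CPM, log2 ratio 6.27, 95% counting interval 5.78 to 6.80), followed by the tubulin TUBA1A (5.61), FILIP1L, KLHL24 (5.51) and QPRT (4.84). The lowest were HMGA2 (-5.08), the EGFR ligand AREG (188 to 5.84 CPM, -5.01), KRT6A (-4.91), S100A2 (-4.46) and MYEOV (-4.44). MKI67 stood at -2.27 (-2.36 to -2.17), DUSP6 at -3.56, EGFR at -1.22, ERBB3 at 1.41 and IGF1R at 1.18. The PC-9 bulk changes of these genes at day 3 had the same signs but were smaller, and IGF1R did not pass there. The PC-9 G2/M median was also smaller in bulk at day 3. The lines therefore lay further apart in that list in bulk than in these sums. In SK-MEL-28 the highest were LINC01933 (8.75, 8.05 to 9.56), SERPINF1 (4.94), TYRP1 (6.61 to 179 CPM, 4.76), PCSK2 (4.28) and DCT (252 to 4570 CPM, 4.18), and the lowest were UCN2 (148 to 0.0868 CPM, -10.74), FOSL1 (-7.91), TNC (-6.93), HECW2-AS1 (-6.89) and GJB1 (-6.49). MLANA stood at 1.44, MITF at 0.57, NGFR at -5.14 (4 UMIs at 72 h, -7.04 to -3.74) and MKI67 at -4.88. ERBB3, which rose in bulk at day 3, stood at -0.19 (-0.26 to -0.12), and MET at -0.06 (-0.22 to 0.10). Both were smaller in size than the 0.31 by which TMM factors raise these ratios, so no direction is given for either. Across genes, the single-cell ratios at 72 h correlated with the bulk changes at day 3 with Pearson r = 0.785 in PC-9 (rho 0.764, 7824 genes) and 0.902 in SK-MEL-28 (rho 0.862, 7792 genes). Against the bulk changes at day 9, r was 0.769 in PC-9 and 0.47 in SK-MEL-28. Genes are not independent replicates, so no p is given.

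Clustering at a resolution of 0.5 gave 13 clusters in PC-9 and 15 in SK-MEL-28, most of them holding cells of mainly 1 library, as time and library coincide. PC-9 cluster 1 held 59.21% of untreated cells. Its leading genes included CLSPN and ATAD2 of S phase, but also AREG, TGM2 and HMGA2, which were lower in gefitinib. It was not read as an S-phase cluster. Clusters led by G2/M genes held 15.71% of untreated PC-9 cells each in clusters 7 and 8, while cluster 5 held 19.62% of cells at 24 h, 5.38% at 48 h and 0.29% at 72 h. Cluster 6, led by PCNA, FEN1 and RFC4, held 11.4% at 24 h, 10.92% at 48 h and 0.23% at 72 h. Cluster 9, led by UBE2S, BOD1, TMEM160 and CCDC85B and with CENPA among its leading genes, held 19.27% of cells at 72 h. The G2/M-high share at that time was 5.42%, so cluster 9 was not read as cycling throughout. That share exceeds those of clusters 5 and 6 at 72 h, so most G2/M-high cells lay in other clusters. Whether cluster 9 held them was not examined. In SK-MEL-28 the cycling cluster 7 held 23.71% of untreated cells, and cluster 14 held 2.43% at 24 h, 1.14% at 48 h and 0.7% at 72 h. SK-MEL-28 cluster 4, led by PHKG1, CTNNB1 and HNRNPH1, held 13.08, 20.61 and 12.87% of cells at 24, 48 and 72 h, with a median of 8087 UMIs per cell. Cluster 10, also led by CTNNB1, PHKG1 and HNRNPH1 among others, held 13.04% of untreated cells, with a median of 9078 UMIs. The same genes were among the leading genes of PC-9 clusters 10 and 11. These held 7.08% of PC-9 cells at 24 h and 5.04% of untreated PC-9 cells, with medians of 11896 and 8945 UMIs. Another cluster of 404 SK-MEL-28 barcodes, with a median of 5842 UMIs, held 20.13% of the untreated library.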

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

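The tests of another cell type by SOX10 and MLANA, of PC-9 cells, of median-of-ratios scaling, of mitochondrial-encoded transcripts, of free RNA and of shallow sequencing, and the counts of other splits, were chosen only after the result was seen.

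In SK-MEL-28 at day 9, mesenchymal and YAP/TEAD genes rose and pigment genes fell. Another cell type in place of part of the melanoma cells, with no other change, would lower SOX10 and MLANA alike. SOX10 fell less, the log2 changes differing by 0.96, which argues against replacement alone. Replacement together with a change in the melanoma cells is left open by it. Markers of PC-9 cells (EPCAM, CDH1, KRT19 and ELF3) stood at a median of 0.04% of their PC-9 level, which argues against PC-9 cells in these cultures. The median-of-ratios factors lay between 0.983 and 1.031, and with them the mesenchymal median was 2.12, which argues against a few abundant genes setting the scale. A change of state within the melanoma cells may account for the pattern, as a hypothesis from the same data, and selection of cells already in that state was not tested.

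Between day 3 and day 9 of PC-9, more genes were lower than higher. With TPM rescaled without mitochondrial-encoded genes 72.7% of the called genes were higher, so the balance depends on whether these transcripts are counted. Their share was larger at day 9, so leaving them out raises all other genes there by construction. The rescaling therefore cannot tell whether that share is the cause. With median-of-ratios factors 709 genes were higher and 849 lower. Leaving out 1 library gave at most 31.3% higher, which argues against a single library. Whether the larger share reflects the cells or the RNA was not tested.

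In untreated SK-MEL-28 single cells, 391 of 1937 barcodes had under 2% mitochondrial counts, with a median of 5879 UMIs against 20536. MALAT1 was lower in them by a log2 ratio of -4.98, which leaves free RNA open, as its own MALAT1 level was not measured. Against barcodes of matched depth the ratio of MALAT1 and NEAT1 was -5.29, which argues against shallow sequencing of whole cells, and MLANA, PMEL, SOX10 and MITF differed by -0.20, which argues against another cell type. The nuclear RNAs KCNQ1OT1, TUG1, PVT1 and LINC-PINT stood at -3.0, so cell fragments without a nucleus may be the source, or free RNA from the cytoplasm. These 4 RNAs were used because the other planned ones are absent from the single-cell table.

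The other splits were compared for each bulk count. In each comparison of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, and 10 splits cannot give a share under 0.05. The real count and the highest other were 6806 and 2 for PC-9 day 3, 6597 and 4 for day 9, and 1274 and 6 for day 9 against day 3. For SK-MEL-28 they were 9606 and 7, 9209 and 5, and 8816 and 6. For the line difference 2 of 100 splits gave as many genes at each day, with 8387 real and 10579 highest at day 3, and 8000 and 10117 at day 9. In the split with the higher count, treated and untreated were exchanged in all SK-MEL-28 libraries and in 0 of PC-9, so that it tests the sum of the 2 responses. Splits that mix treated and untreated libraries break the drug response itself, so the share of 0.02 cannot test whether the lines responded equally. It argues only against no response in either line.

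The line difference, SK-MEL-28 minus PC-9, at day 3 had list medians of -2.25 for MAPK output, -1.41 for S phase, -2.36 for G2/M, -0.58 for WNT, -0.75 for YAP/TEAD, -1.15 for interferon-stimulated genes, -1.34 for antigen presentation and -1.97 for NF-kB. Those of pigment cell genes, cholesterol synthesis, glycolysis, the respiratory chain, ribosomal proteins, ribosome biogenesis, the integrated stress response and the unfolded protein response were 0.89, -1.55, -0.96, -0.30, 0.28, -0.53, 0.32 and -0.98. The largest gene terms at day 3 were SNORD22 (6.28, a short RNA, with adjusted p = 0.0915 without a filter and up to 0.118 without 1 library), LINC01933 (5.51), SERPINF1 (5.18), PRUNE2 (5.06) and TYRP1 (4.95), and the pseudogenes HMGN2P3 (-7.19) and TMSB4XP6 (-7.04), UCN2 (-6.36), ALDH1A3 (-6.07) and HECW2-AS1 (-5.77). The terms of LINC01933, TYRP1 and HECW2-AS1 equal their changes in SK-MEL-28, so PC-9 adds nothing to them.

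At day 9 the list medians of the line difference were -1.07 for MAPK output, -0.53 for S phase, -0.74 for G2/M, 0.18 for receptor tyrosine kinases, 0.29 for growth factor ligands, 0.78 for YAP/TEAD, -1.23 for interferon-stimulated genes, -1.79 for antigen presentation and -1.24 for NF-kB. Those of mesenchymal, pigment, neural crest, lysosome, cholesterol synthesis, respiratory chain, ribosome biogenesis, integrated stress response and unfolded protein response genes were 0.75, -1.54, 1.10, -0.52, -1.59, -0.22, 0.18, 0.94 and -0.46. The largest gene terms at day 9 were LINC00968 (7.08), CRYAB (6.48), CPA4 (6.19), SLITRK6 (5.94) and PRUNE2 (5.68), and CD74 (-7.58), PLA1A (-7.25), CASP1 (-7.08), GJB1 (-6.69) and UCN2 (-6.63). The term of LINC00968 equals its change in SK-MEL-28, so PC-9 adds nothing to it.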

How the results depend on the processing

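The alternatives chosen only after results were seen were median-of-ratios scaling, a pseudocount of 0.1, rescaling without mitochondrial-encoded genes and leaving out barcodes under 2% mitochondrial. The planned edgeR and DESeq2 bulk tests and the DESeq2 change were not run, as they need counts. Of 236 named results 33 changed their call in some setting and 203 never did, and 1 turned its direction, AXL in the line difference at day 3 (-0.11 with a pseudocount of 0.1). With a change of at least 1 required, the counts of changed genes were 1251, 1187 and 87 in PC-9 (day 3, day 9, day 9 against 3), 3050, 2728 and 2429 in SK-MEL-28, and 3120 and 2999 for the line difference. Shared genes then numbered 289 between lines at day 9, 277 at day 3, 836 within PC-9 and 1246 within SK-MEL-28. Leaving out replicate 1 or replicate 2 of every group gave 1770 or 2427 shared genes between lines at day 9 (3163 with all), 2141 or 2812 at day 3 (3459) and 3138 or 4326 within PC-9 (5163). For PC-9 day 9 against day 3 the count was 839 without a filter, 820 with a replicate block and 591 with only the groups compared, from 539 without day 3 replicate 3 to 2279 without day 9 replicate 2. The same replicate number did not pair libraries, with correlations of deviations between -0.05 and 0.055 in PC-9 and between -0.044 and 0.079 in SK-MEL-28. With an estimated correlation 0, 0 and 0 of the 32 biology lists passed in PC-9, 3, 7 and 3 in SK-MEL-28, and 8 and 2 for the line difference. By fry, which tests against no change, 28, 28 and 27 passed in SK-MEL-28 and 29 for the day 3 line difference. The G2/M-high share at 0, 24, 48 and 72 h with a minimum of 15 UMIs was 84.0, 33.57, 13.87 and 9.86% in PC-9, and 43.03 and 3.66% at 0 and 24 h in SK-MEL-28. With 40 UMIs it was 13.97, 11.75, 2.6 and 2.02% in PC-9 and 14.38, 1.83, 0.67 and 0.44% in SK-MEL-28. The correlation of single cells with bulk was 0.762 in PC-9 at 1 CPM or more. In SK-MEL-28 it was 0.886 at 1 CPM or more, 0.91 at 50 CPM or more and 0.894 without barcodes under 2% mitochondrial. At a resolution of 0.3 SK-MEL-28 had 8 clusters. With TMM factors 12 lists had a median above 0 in SK-MEL-28 at 72 h, against 7. The cause was not tested.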

Other observations

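The comparisons of G2/M-high cells with the other cells were chosen only after results were seen, and the lists were fixed before. BCL2 family genes split in SK-MEL-28 at day 3, with 7 higher and 7 lower of 16 (camera adjusted p = 0.752), among them BBC3 (2.34), BCL2L11 (2.08) and BMF (2.07) higher and PMAIP1 (-2.74) and BID (-0.83) lower. In PC-9 at day 3, 5 of 14 rose, BMF (1.72), BBC3 (1.63), PMAIP1 (0.76), BCL2L11 (0.71) and BOK (0.70), and 1 fell, BCL2L1 (-0.65), while the list did not pass (adjusted p = 0.211). Aldehyde dehydrogenase and ABC exporter genes split into 4 higher and 5 lower of 14 in SK-MEL-28 at day 3 (adjusted p = 0.761). ALDH1A3 fell by 4.92 in SK-MEL-28 at day 3 and rose by 1.15 in PC-9, a line difference of -6.07. Histone methylation enzymes did not pass as a list in either line at day 3 (adjusted p = 0.798 in PC-9 and 0.329 in SK-MEL-28), and EZH2 fell in both (-0.67 and -1.86).

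At 72 h, G2/M-high PC-9 cells (94, against 1641 others) had a median log2 ratio of 0.84 for ribosome biogenesis, 0.51 for interferon-stimulated genes and -0.54 for FOXO-associated genes. These lists stood at 0.18, -0.04 and 0.02 in untreated PC-9, and at 0.19, 0.62 and -0.15 in SK-MEL-28 at 72 h. In SK-MEL-28 at 72 h (23 against 3150 cells) the median was 1.07 for the 6 NF-kB targets measured and -0.78 for pigment genes. The pigment median was -0.17, -0.09 and -0.32 at 0, 24 and 48 h, and NF-kB targets stood at -0.12 in untreated SK-MEL-28 (518 against 1290 cells, 7 genes) and at -0.09 in PC-9 at 72 h. Each contrast lies within 1 library, so it has no replicate. A gene was measured if it passed a minimum in either sum, so low genes can enter by a few UMIs in the smaller group. That can raise a median, most of all with 23 cells. In SK-MEL-28 at 72 h NOTCH pathway genes stood at 0.75 and growth factor ligands at -0.01. The NF-kB value there is therefore not read as a difference between the cells.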
